A study of Mus musculus with 24 samples.

How the data were processed

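The series holds 24 samples of whole adrenal glands of adult male C57B/6J mice, 2 for each of 12 time points from 38 to 82 h after lights off. Per the labels' protocols, mice were kept for 2 weeks in cycles of 12 h light and 12 h darkness and killed in constant darkness, and total RNA was extracted with a column kit and labelled with biotin. The values used here are the probe set intensity values that the authors deposited for Affymetrix mouse genome arrays, on a linear scale. How the authors summarised and scaled them is not given in the sources used here. Array medians of the log2 values lay between 8.14 and 8.32, a range of 0.18, which is under the 0.2 set in advance, so that no further normalization was applied. Arrays give signals and not read counts, so the number of arrays limits the precision, and no depth applies.

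Values were analysed as log2(intensity + 51), where 51 is the 10th percentile of all deposited values, so fold changes of dim genes are understated. Of 45101 probe sets, 64 were controls. In the platform's annotation 34958 probe sets had 1 gene symbol, 932 had several, and 9211 were not listed and are unnamed here. Through their gene identifiers 34754 of the named probe sets were found in the reference gene table, and 0 symbols changed. Probe sets whose mean lay under the 40th percentile (a signal of 184) were left out, and each gene was represented by its brightest remaining probe set, which left 13879 genes. Of the named genes 48 had other tested probe sets, 87 in all. Of these, 48 gave the same call with a peak within 4 h or the same absence of a call, 36 were not past the threshold while the chosen one was, and 3 the reverse.

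Samples were grouped by the hours after lights off in their labels, and projected circadian time was these hours minus 12, modulo 24. Before averaging, all pairs of columns were compared, and the rule for near-copies was set after the data were seen. In 6 pairs all ratios of probe sets with a signal of at least 50 lay within 5%, and each such pair was averaged on the log2 scale and counted as 1 sample. Tests therefore ran on 18 profiles, 3 per circadian time, and not on the 24 columns planned before the data were examined. For the same reason the test of any difference ran over 6 circadian times and not over 12 time points, and the comparisons of cycles used 13 profiles. Counts over all 24 columns are given as an alternative. A fit with 24 columns is too liberal here: of 50 random orders of the samples within batches, 26 gave at least 1 call over 24 columns (mean 116, highest 2042), and 3 did over 18 profiles (mean 0.72, highest 34).

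Array batches were defined after the data were seen, from the ThrX-3 control, with a threshold signal of 300 that no array lay near. The second batch holds circadian times 10 and 18 alone, 6 profiles, and the first batch the other 4 circadian times, 12 profiles. A batch term can be fitted beside a 24 h cosine but not beside free levels of the 6 circadian times. The fit with the batch as a block, the fit within the first batch and the difference between circadian times 18 and 10 within the second were therefore added after the data were seen. So were fits without the profile of 78 h replicate 2, which has a low ratio of 5' to 3' Gapdh signal, and without 4 profiles with an Acta1 signal over 1000.

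Rhythms were tested with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8): a moderated F test, with trend, on the cosine and sine of a 24 h period. Amplitude is the distance from the fitted mean to the peak, in log2 units, with its SE, and the peak-to-trough ratio follows from it. P-values were adjusted over the 13879 genes by Benjamini-Hochberg, with a threshold of 0.05. In the same way limma tested differences between circadian times, level differences between cycles with circadian time as a factor, the interaction of cycle with cosine and sine, and a 12 h cosine and sine beside the 24 h terms. Gene lists, 22 in all, were fixed before the data were examined. Each list of at least 3 tested genes (21 lists) had permutation tests with 100000 permutations of the profiles, one-sided, of the mean share of variance explained by the 24 h cosine (any phase) and of that share for the mean of the members (common phase). Profiles were permuted within batches for the blocked test. Their p-values were adjusted over the lists, and 1e-05 is the smallest p that these permutations can give before adjustment, so an adjusted 3.5e-05, 0.000105 or 0.00021 rests on that smallest p. Fisher's exact test, two-sided, compared the rhythmic share of a list with that of all other genes.

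The genes named were chosen by a rule fixed before the data were examined: all tested members of the core clock and steroid synthesis lists, the 12 largest amplitudes past the threshold with a similar peak in both replicate sets, up to 4 members with the lowest p of each list with a rhythmic gene, and the 5 genes with the lowest p for the tests of cycles and of the 12 h component. Predicted genes were left out. The 12 largest amplitudes with the batch as a block were added after the data were seen, and so were single genes named in the text for their levels as tissue markers.

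The scripts were tested on simulated data of the same 13879 genes and 18 profiles, with 50 rhythmic genes at each amplitude. Without batch shifts, the 24 h test found 33, 47, 50 and 50 of 50 for amplitudes 0.25, 0.5, 1 and 1.5, with 8 of 13679 other genes called. With batch shifts added and the batch as a block it found 31, 46, 50 and 50, with 11 others called. With batch shifts added and no block, as in the main fit, it found 24, 45, 49 and 49, with 9 others called. Without batch shifts, 193 of 200 simulated 12 h components with an amplitude of 0.5 were found. Batch shifts were not simulated for this test. In the real order its 12 h terms carry 0.333 of the batch difference left by the 24 h terms, so this rate may not hold there.

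Alternatives fixed before the data were examined were no filter and a stricter filter at the 60th percentile, quantile normalization, arrays centred on their medians, offsets of 1 and 204, all probe sets, probe sets without cross-hybridization marks, each array and each replicate number left out, limma without trend, an ordinary F test, means of each time point, the time point as a random block, the replicate number as a block, the cycle as a covariate, and periods slightly shorter and longer than 24 h. No column of per-sample values was left unused. Probe sets with several symbols or none, 932 and 9211 of them, are in no gene result. Genome coordinates were not used here.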

Results

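Transcript levels were measured on Affymetrix mouse arrays in whole adrenal glands of adult male C57B/6J mice. The mice had lived in alternating 12 h of light and darkness and were then left in constant darkness, so that rhythms driven by the circadian clock could be told from responses to light. Glands were collected at 12 time points, every 4 h from 38 to 82 h after lights off, with 2 arrays per time point and 24 arrays in all. The series covers 6 projected circadian times (2, 6, 10, 14, 18 and 22) in 2 consecutive cycles, where circadian time 0 is the hour at which lights would have come on. The labels do not say whether the arrays of a time point came from separate animals, so p-values measure only the spread between these samples, which may be technical. The median probe set signal per array lay between 8.14 and 8.32 on the log2 scale, and the number of arrays limits the precision.

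In 6 pairs of arrays the deposited values differed by less than the noise between arrays. Within each of these pairs every probe set with a signal of at least 50 agreed within 5%, and the SD of the log2 ratio was 0.042 at most. It was between 0.22 and 0.52 in the 30 other pairs of the same circadian time. Of the 6 pairs, 5 joined time points 24 h apart and 1 joined both arrays of 70 h. Each pair was counted as 1 sample, which left 18 profiles, 3 at each circadian time. A pair that spans both cycles belongs to neither, so 13 profiles had a clear cycle, 7 in the first and 6 in the second.

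The 8 arrays of 46, 54, 70 and 78 h, which are all arrays of circadian times 10 and 18, differed from the other 16 in control probe sets. ThrX-3, a probe set for a bacterial control RNA, read 513 to 1858 on these 8 arrays and 56.3 to 101 on the others. ThrX-5 and ThrX-M, other probe sets for the same control, did not rise with it. They averaged 7.31 and 8.81 (log2) on the other arrays and 7.08 and 8.56 on these. The signal of ThrX-3 thus does not show that the amount of this control differed, and its source was not tested. The 18S ribosomal RNA control read 606 to 2652 against 5150 to 6357. The ratio of 5' to 3' Gapdh signal, a measure of RNA integrity and labelling, was 0.0386 to 0.978 on these arrays and 1.03 to 1.15 on the others. These sets are called the second and the first array batch, with 6 and 12 profiles. Acta1, the skeletal muscle actin, lay between 6.03 and 6.78 (log2) in the first batch and between 6.37 and 12.98 in the second. Alb, the liver product serum albumin, lay between 6.95 and 10.29 in the first batch and between 9.63 and 13.08 in the second, and the haemoglobin gene Hba-a1 between 7.87 and 8.32 against 8.64 and 10.16. Of the 13879 genes tested, 2466 were higher and 4112 lower on average in the second batch (limma), a difference that includes any rhythm. Rhythms are therefore given without a batch term, with the batch as a block, and within the first batch (circadian times 2, 6, 14 and 22). Values for the second batch are given as circadian time 18 minus 10. The arrays of these times also differed in tissue and RNA. Alb lay between 9.68 and 13.08 (log2) at circadian time 18 and between 9.63 and 9.94 at 10. The Gapdh ratio of 0.0386 belongs to 78 h replicate 2, at circadian time 18. This contrast was not repeated without that array, so it may include such differences wherever it is given below.

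**Figure D1:**
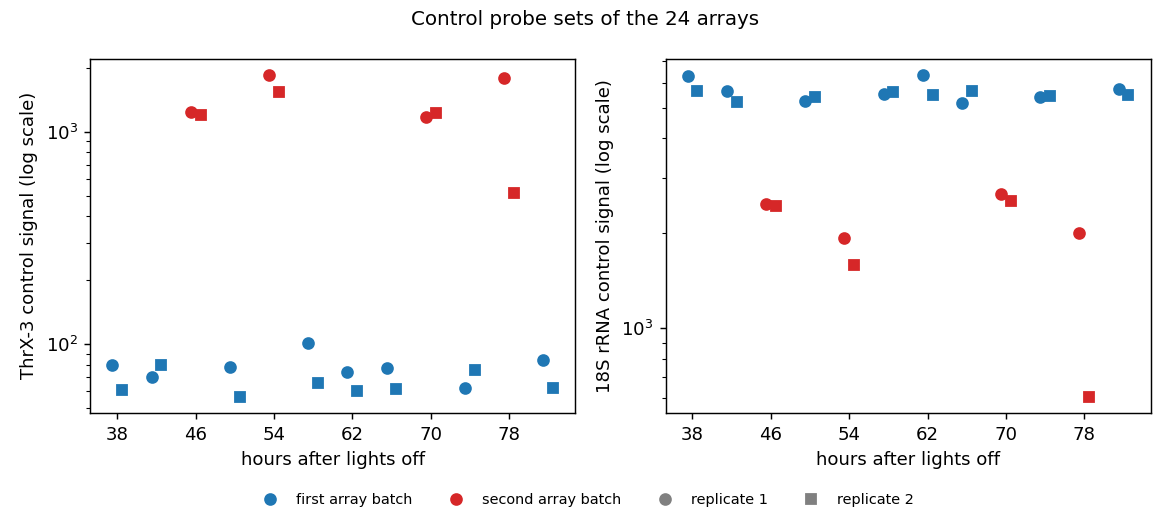
Signal of the bacterial control ThrX-3 (left) and of the 18S ribosomal RNA control (right) on each of the 24 arrays, on log axes, against hours after lights off; circles are replicate 1, squares replicate 2, and colours the array batches. The 8 arrays of 46, 54, 70 and 78 h lie between 513 and 1858 for ThrX-3, all above the other 16.

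The first question was which genes followed a 24 h rhythm, and the genes of the clock itself had some of the largest rhythms. Arntl, which encodes the clock activator BMAL1, had a mean log2 signal of 11.01 ± 0.09 at circadian time 22 and of 5.99 ± 0.55 at circadian time 10 (SD, n = 3 each). At circadian time 10, 2 of 3 profiles stood at 5.67, where a signal of 0 lies after the offset, so the depth of this trough was not measured. Its fitted amplitude of 2.18 ± 0.24 log2 units (SE, n = 18 profiles), with a peak at circadian time 22.5 (limma, adjusted p = 6e-05), therefore depends on the offset, and was 3.58 with an offset of 1 and 1.54 with a 4 times larger one. Within the first batch, which lacks that time, it was 1.56 (adjusted p = 6.88e-05). Nr1d1, which encodes the Arntl repressor REV-ERB alpha, peaked at circadian time 7.28 with an amplitude of 1.77 ± 0.14 (adjusted p = 3.11e-06). Its relative Nr1d2 followed at 10.3 with 1.33 ± 0.10 (adjusted p = 1.35e-06). The repressor Per2 peaked at 13.7 with 1.15 ± 0.10 (adjusted p = 4.11e-06), and the repressor Cry1 at 18.1 with 1.28 ± 0.09 (adjusted p = 6.6e-07).

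Of 16 tested genes of the core clock loop, 11 were rhythmic over all genes and 12 when adjusted over the list alone. The other 6 past the threshold were Per1, Cry2, Clock, Bhlhe40, Ciart and Csnk1e, with amplitudes from 0.29 ± 0.07 for the kinase gene Csnk1e to 0.74 ± 0.14 for Per1. Npas2, Csnk1d, Rora, Per3 and Bhlhe41 did not pass, with adjusted p from 0.0531 for Npas2 to 0.582 for Bhlhe41. Another Per3 probe set passed only with the block (limma over all probe sets, amplitude 0.18, adjusted p = 0.0329, and 0.991 without it). The remaining Per3 probe sets passed in neither fit. On the brightest probe sets the same 11 genes passed with the batch as a block. Amplitudes were then 1.95 ± 0.16 for Arntl, 1.81 ± 0.13 for Nr1d1, 1.26 ± 0.10 for Per2 and 1.27 ± 0.09 for Cry1. Within the first batch 8 of the 16 passed, without Bhlhe40 (adjusted p = 0.111), Ciart (0.08) and Csnk1e (0.0981). In the second batch Cry1 was 1.55 log2 units higher at circadian time 18 than at 10, Nr1d1 fell by 3.09, and Arntl was higher at 18 (adjusted p = 0.00283) by an amount that the trough at the floor leaves open. The rhythmic share of the list exceeded that of all other genes (Fisher's exact test, two-sided, adjusted p = 2.23e-06; 5.64e-05 with the block). Permutation of the profiles, one-sided, gave an adjusted p of 3.5e-05 for a rhythm in any phase, from the smallest p it can give, and of 0.00161 for a rhythm of the list mean.

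**Figure D2:**
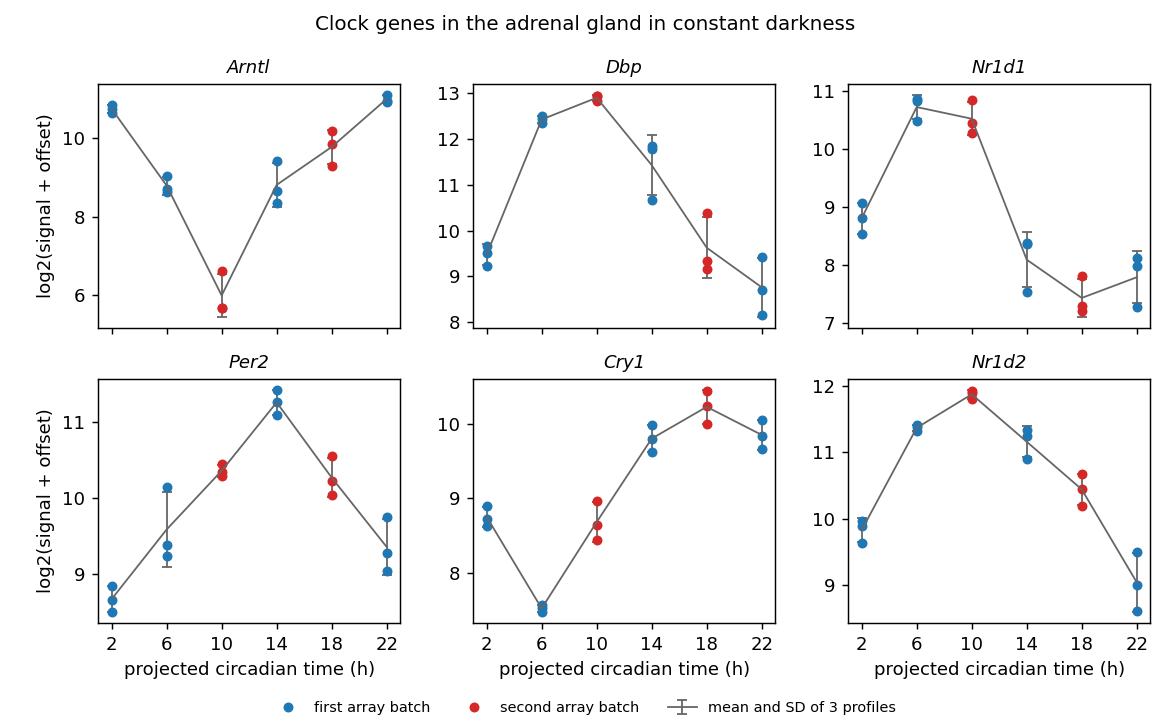
Log2 signal of 6 clock genes against projected circadian time; points are the 18 profiles, coloured by array batch, and the line joins means with SD of 3 profiles. Arntl is lowest at circadian time 10, at 5.99 ± 0.55, and Dbp highest there, at 12.90 ± 0.07.

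Genes listed in advance as PAR bZIP factors or other clock output mostly cycled as well. Dbp, a PAR bZIP activator, had an amplitude of 2.18 ± 0.16 (SE, n = 18), a ratio of 20.7 and a peak at circadian time 9.57 (limma, adjusted p = 7.64e-07; blocked amplitude 2.17 ± 0.16). Tef, its relative, peaked at 12.4 with an amplitude of 0.93 ± 0.05 (adjusted p = 6.25e-08), and Nfil3, a repressor at D-box elements, at 18.9 with 0.96 ± 0.13. Wee1, a kinase that restrains entry into mitosis, peaked at 13.3 with 0.55 ± 0.06. Tsc22d3, a glucocorticoid-induced gene, peaked at 15.1 with 0.54 ± 0.05 on a probe set marked for cross-hybridization, and on its brightest unmarked one it did not pass (amplitude 0.24, adjusted p = 0.439; over all probe sets with the block 0.54 and 0.00376). Of 14 tested genes of this list 11 were rhythmic, 13 when adjusted over the list alone, 11 with the block and 10 within the first batch. Their mean peaked at circadian time 12.5 (permutation test, adjusted p = 0.00021; 0.00014 with the block; 0.00105 within the first batch), and their rhythmic share exceeded that of other genes (Fisher's exact test, adjusted p = 4.17e-07; 8.92e-06 with the block). Dbp fell by 3.27 log2 units from circadian time 10 to 18 in the second batch, where Nfil3 was 1.28 higher at 18.

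Over all genes, 1781 of 13879 (12.8%) had a 24 h rhythm at an adjusted p under 0.05, and 4287 had an unadjusted p under 0.05. With the array batch as a block 2475 genes passed, and 1703 within the first batch. A set of 1531 genes passed with and without the block, and for 1521 of them both peaks lay within 2 h. Another 250 passed only without the block and 944 only with it. In all 3 fits 957 genes passed. The blocked count was 1926 without 4 profiles with muscle transcripts and 2543 without 78 h replicate 2, the array with a low 5' signal of Gapdh. The count fell to 1178 without the replicate 1 array of 46 h, to 955 over time point means and to 537 with the time point as a random block. It was 26 without replicate 1 and 152 without replicate 2, which leaves 12 arrays, and 4193 when all 24 arrays were taken as independent, in which 6 near-copies count again.

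Besides Dbp, Arntl, Nr1d1, Nr1d2, Cry1 and Per2, the 12 genes with the largest amplitudes were Hoxd13, Col5a3, Fabp7, Cirbp, Fmo2 and Cryba4. Fabp7, a fatty acid binding protein gene, peaked at circadian time 3.2 with an amplitude of 1.08 ± 0.12, and the collagen gene Col5a3 at 0.564 with 1.21 ± 0.13. Fmo2, a flavin monooxygenase gene, peaked at 15.9 with 0.99 ± 0.09, and the crystallin gene Cryba4 at 22.8 with 0.97 ± 0.14 (0.81 ± 0.10 with the block and 0.62 within the first batch). Mean levels in the second batch differed by -1.37 log2 units for Col5a3, -1.09 for Cryba4 and 0.84 for Fmo2. For Hoxd13, a homeobox gene, the amplitude was 1.34 ± 0.31 without the block and 0.66 ± 0.15 with it, and its mean level was 2.56 log2 units higher in the second batch. The other tested probe sets of Arntl, Col5a3 and Hoxd13 did not pass the limma test over all probe sets. Their amplitudes were 0.14, 0.06 and 0.09 (adjusted p = 0.191, 0.742 and 0.324, and with the block 0.293, 0.889 and 0.357). With the block, a list chosen by the same rule after the data were seen also held Slc6a2, Tfrc, Cyp51 and Nfil3. Slc6a2, the noradrenaline transporter gene, had a blocked amplitude of 1.32 ± 0.20 (adjusted p = 0.000625) and 0.82 ± 0.27 without the block (adjusted p = 0.113). Its other tested probe sets had blocked amplitudes of 0.04, 0.11 and 0.19, and only the last passed (limma over all probe sets, adjusted p = 0.0338). Tfrc, the transferrin receptor gene, rose to a peak at 15.6 with a blocked amplitude of 1.18 ± 0.14 (adjusted p = 0.00011).

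Most rhythms were small, with a median amplitude of 0.24 log2 units and a median ratio of 1.39 (0.22 and 1.35 with the block). A peak-to-trough ratio of 2 or more was reached by 127 genes (175 at an unadjusted p under 0.05), by 124 with the block, and by 95 in both. That count was 191 without the profile of 50 h replicate 1 and 74 h replicate 2, and 76 with a 4 times larger offset, which shrinks ratios of low signals. Peak times were spread over the day: between circadian times 4 and 8 lay 22.9% of the 1781 peaks, and the other 4 h bins held 13.4% to 17.5%. With the block, the bins of 4 to 8 and 16 to 20 held 26.7% and 23.2% of the 2475 peaks, and the others 10.3% to 14.2%. In units of the residual SD, the block widens the SE of an amplitude from 0.333 to 0.385 for peaks at circadian times 2 and 14 and leaves it at 0.333 for peaks at 8 and 20.

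**Figure D3:**
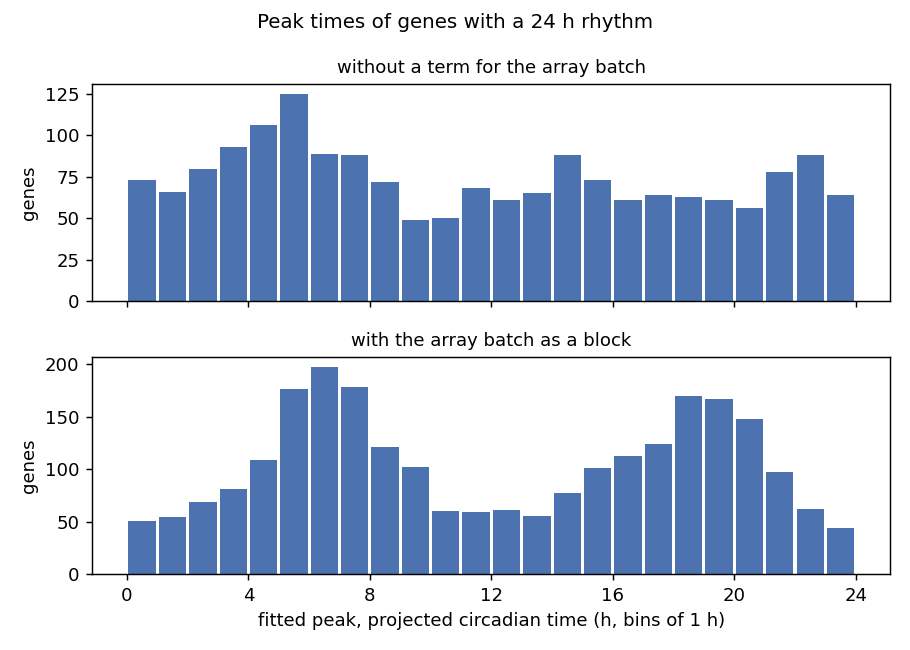
Number of genes with a 24 h rhythm per 1 h bin of the fitted peak (projected circadian time), without a batch term (top, 1781 genes) and with the array batch as a block (bottom, 2475 genes). With the block, 26.7% of peaks lie between 4 and 8 and 23.2% between 16 and 20.

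Enzymes of cholesterol synthesis, which supplies the substrate of steroid hormones, rose together in the projected night. Cyp51, the lanosterol demethylase, went from 9.36 ± 0.26 at circadian time 6 to 11.07 ± 0.15 at circadian time 14 (log2, SD, n = 3 each), with a fitted amplitude of 0.93 ± 0.09 and a peak at 17.8 (limma, adjusted p = 9.96e-06). Sqle, the squalene epoxidase, peaked at 17.7 with an amplitude of 0.84 ± 0.07 and Msmo1 at 17.2 with 0.57 ± 0.06. Hsd17b7 peaked at 17.0 with 0.86 ± 0.07 on a probe set marked for cross-hybridization, and on its brightest unmarked one the amplitude was 0.26 and did not pass (adjusted p = 0.186; over all probe sets with the block 0.44 and 0.000658). Of 19 tested genes 15 were rhythmic, also when adjusted over the list alone, 17 with the block and 15 within the first batch. The list mean peaked at circadian time 18 with an amplitude of 0.42, and with the block at 17.3 with 0.47 (permutation test, adjusted p = 0.00115 and 0.000105; 0.00063 within the first batch). In the second batch 10 of the 19 differed between circadian times 10 and 18, and the median member was 0.56 log2 units higher at 18. The rhythmic share exceeded that of other genes (Fisher's exact test, adjusted p = 2.05e-09; 2.32e-10 with the block).

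For cholesterol uptake and storage, 2 of 11 tested genes were rhythmic, also when adjusted over the list alone, with 3 under the block and 3 within the first batch. Abca1, which exports cholesterol from cells, peaked at circadian time 3.91 with an amplitude of 0.50 ± 0.06 (limma, adjusted p = 0.000283; 0.00047 with the block). Npc1, which moves cholesterol out of lysosomes, peaked at 11.4 with 0.22 ± 0.05 (adjusted p = 0.0135). The permutation test over the list passed for any phase (adjusted p = 6e-05; 0.000131 with the block; 0.0175 within the first batch) and not for a common phase (0.23; 0.112 with the block). The rhythmic share did not differ detectably from that of other genes (Fisher's exact test, adjusted p = 0.831; 0.625 with the block).

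On their brightest probe sets, genes of steroid synthesis itself mostly did not pass. Stard4, a carrier of cholesterol, was the 1 rhythmic gene of 12 tested, also when adjusted over the list alone (2 with the block, 1 within the first batch). Its amplitude was 0.46 ± 0.07, with a peak at circadian time 17.1 (limma, adjusted p = 0.00106, and 0.000343 with the block). Its other tested probe set passed over all probe sets only with the block (limma, amplitude 0.32, adjusted p = 0.032, and 0.23 and 0.648 without it). Nr5a1, the steroidogenic transcription factor SF-1, had an amplitude of 0.24 ± 0.07 (adjusted p = 0.0714; 0.29 ± 0.08 and 0.0334 with the block), and Nr0b1 0.19 ± 0.07 (adjusted p = 0.154; 0.12 ± 0.07 and 0.423 with the block). Tspo had 0.27 ± 0.09 (adjusted p = 0.12) and, with the block, 0.10 ± 0.03 (adjusted p = 0.102), and its mean level in the second batch differed by -0.67 log2 units. A Tspo probe set marked for cross-hybridization passed over all probe sets (limma, amplitude 0.09, adjusted p = 0.0231, and 0.07 and 0.0452 with the block). Another marked one did not (adjusted p = 0.0553, and 0.101 with the block). Star, which carries cholesterol into mitochondria, had an amplitude of 0.07 ± 0.02 (adjusted p = 0.14; 0.0618 with the block), and Cyp11a1, the side chain cleavage enzyme, 0.09 ± 0.04 (adjusted p = 0.274; 0.01 ± 0.03 and 0.98 with the block). In the limma test over all probe sets, another Cyp11a1 probe set passed with an amplitude of 0.30 (adjusted p = 0.0451, and 0.0753 with the block). Another Star probe set passed only with the block (amplitude 0.08, adjusted p = 0.0167, and 0.237 without it). A further Star probe set passed in neither fit (adjusted p = 0.393, and 0.347 with the block). The mean signals of Star (13.62), Cyp11a1 (13.55), Hsd3b1 (13.66), Fdx1 (13.64) and Cyp11b1 (13.42) lay close to the highest signal of any probe set, 13.67 to 13.81 per array. The list passed the permutation test for any phase (adjusted p = 0.00202; 0.000131 with the block) and for a common phase only within the first batch (0.485 without the block, 0.112 with it, 0.0362 within the first batch). Its rhythmic share was not above that of other genes (Fisher's exact test, adjusted p = 1 without the block and with it).

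Parts of the ACTH receptor pathway, which drives steroid output, were rhythmic at different phases. Mc2r, the ACTH receptor, peaked at circadian time 0.393 with an amplitude of 0.24 ± 0.04 (limma, n = 18, adjusted p = 0.00121; 0.00232 with the block). Mrap, the accessory protein that brings the receptor to the membrane, peaked at 22.1 with 0.48 ± 0.08 (adjusted p = 0.00204), and with the block at 20.7 with 0.41 ± 0.04 (adjusted p = 3.14e-06). The other tested Mrap probe set did not pass over all probe sets (amplitude 0.13 in both fits, adjusted p = 0.259, and 0.298 with the block). Pde8b, a phosphodiesterase that breaks down cAMP, had an amplitude of 0.52 ± 0.07 (adjusted p = 0.000589) and, with the block, a peak at 22.9 and 0.43 ± 0.06, and Prkar2b, a regulatory subunit of protein kinase A, at 15.1 with 0.34 ± 0.05 (adjusted p = 0.000872). Of 19 tested genes 9 passed, also when adjusted over the list alone, as did 9 with the block and 8 within the first batch. The list passed for any phase (permutation test, adjusted p = 3.5e-05; 0.00028 within the first batch) and not for a common phase (adjusted p = 0.74; 0.178 with the block), and Fisher's exact test passed (adjusted p = 0.00112; 0.00931 with the block).

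**Figure D4:**
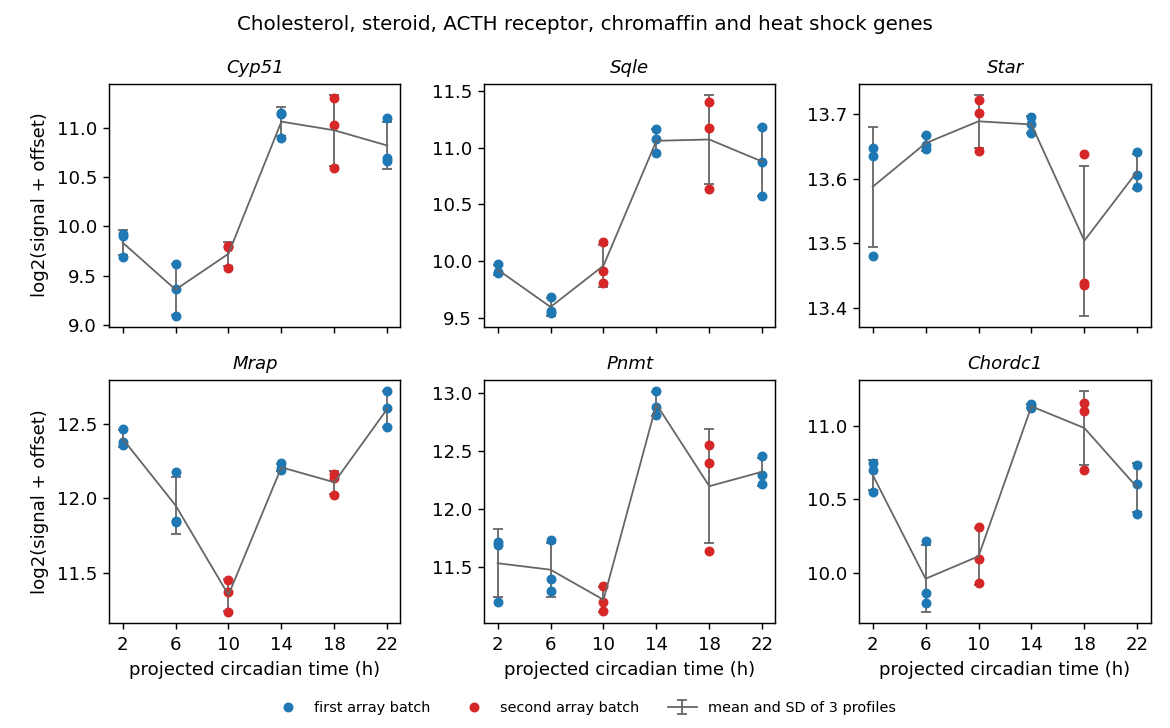
Log2 signal of Cyp51, Sqle, Star, Mrap, Pnmt and Chordc1 against projected circadian time; points are the 18 profiles, coloured by array batch, and the line joins means with SD of 3 profiles. Axes differ between panels, and Star spans 13.50 to 13.69 in its means while Pnmt spans 11.22 to 12.91.

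In the chromaffin cells of the medulla, Pnmt, which converts noradrenaline to adrenaline, was rhythmic with a peak at circadian time 17.6 and an amplitude of 0.66 ± 0.14 (limma, adjusted p = 0.013). With the block its amplitude was 0.86 ± 0.08 and its peak at 16.5 (adjusted p = 7.51e-06), and it passed within the first batch (adjusted p = 5.22e-05). Slc18a2, the vesicular monoamine transporter, peaked at 8.71 with 0.37 ± 0.08, the transcription factor gene Phox2a at 8.49 with 0.30 ± 0.07, and the synaptotagmin gene Syt1 at 11.2 with 0.20 ± 0.05. Of 18 tested genes 6 passed, 9 when adjusted over the list alone, 8 with the block and 3 within the first batch, where Slc18a2 (adjusted p = 0.0562), Phox2a (0.134) and Syt1 (0.12) did not. The list passed for any phase (permutation test, adjusted p = 0.00198; 0.000147 with the block) and not for a common phase (0.361; 0.403 with the block), and 11 of its 18 genes differed in mean level between the batches. By Fisher's exact test its rhythmic share passed only with the block (adjusted p = 0.0223; 0.051 without it).

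Heat shock genes rose in the projected night, opposite to a cold-inducible gene. Chordc1, a partner of HSP90, peaked at circadian time 18 with an amplitude of 0.50 ± 0.09 (limma, adjusted p = 0.00645). Hspe1, a mitochondrial chaperonin held in the same list, peaked at 19.7 with 0.25 ± 0.04 (adjusted p = 0.00156), and its probe set without a cross-hybridization mark gave 0.62 (adjusted p = 0.00645). Dnaja1 and Ahsa1, co-chaperones of HSP70 and HSP90, peaked at 18.3 with 0.34 ± 0.06 and at 19.3 with 0.29 ± 0.05. Of 19 tested genes 12 passed, 13 when adjusted over the list alone, 18 with the block and 13 within the first batch. Their mean peaked at 19.0, and with the block at 17.6 (permutation test, adjusted p = 0.0367 and 0.00441; 0.0469 within the first batch), and the rhythmic share exceeded that of other genes (Fisher's exact test, adjusted p = 2.23e-06; 1.1e-11 with the block). In the second batch 9 of the 19 differed between circadian times 10 and 18, with a median 0.50 log2 units higher at 18. Cirbp, a cold-inducible RNA-binding protein gene, peaked at 6.3 with 1.03 ± 0.12 (adjusted p = 0.000166; blocked amplitude 1.10 ± 0.11). Srsf5, a splicing factor gene, had an amplitude of 0.55 ± 0.14 (adjusted p = 0.04), and with the block 0.36 ± 0.13 (adjusted p = 0.133; 0.271 within the first batch). Thus 2 of 2 cold-inducible genes passed without the block, also adjusted over the list alone, and 1 with it (Fisher's exact test, adjusted p = 0.0453; 0.55 with the block).

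Of 20 tested endoplasmic reticulum chaperone and unfolded protein response genes 9 passed, 10 when adjusted over the list alone, 12 with the block and 10 within the first batch. Herpud1 and Dnajb9, which act in the degradation of misfolded proteins, peaked at circadian times 12.9 and 12.5 with amplitudes of 0.42 ± 0.03 and 0.32 ± 0.05 (limma, adjusted p = 3.66e-06 and 0.00174). The chaperone gene Calr peaked at 18 with 0.17 ± 0.03 (0.10 within the first batch, adjusted p = 0.0397) and the disulfide isomerase gene Pdia6 at 18.7 with 0.23 ± 0.04. The list passed for any phase (permutation test, adjusted p = 3.5e-05; 0.000131 with the block). For a common phase it passed with the block (adjusted p = 0.0128) and within the first batch (0.0164), and not without the block (0.667). Fisher's exact test passed (adjusted p = 0.0015; 0.000135 with the block).

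The glucocorticoid-induced genes that passed peaked at several times of day. Klf9, a transcription factor gene, peaked at circadian time 7.45 with an amplitude of 0.39 ± 0.05 (limma, adjusted p = 0.00063), Dusp1, a MAP kinase phosphatase gene, at 6.6 with 0.41 ± 0.07, and Cdkn1a, the cell cycle inhibitor p21, had an amplitude of 0.41 ± 0.07, with a peak at 22.8 in the blocked fit. Of 16 tested genes 6 passed, 9 when adjusted over the list alone, 6 with the block and 7 within the first batch. The list passed for any phase (permutation test, adjusted p = 3.5e-05) and not for a common phase (0.141; 0.112 with the block). Its rhythmic share passed Fisher's exact test without the block (adjusted p = 0.0354) and not with it (0.101). Tsc22d3 and Per1 are in this list and in a clock list.

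Some immediate early genes were rhythmic, and the 4 named here peaked in the projected day. Jun peaked at circadian time 8.12 with an amplitude of 0.38 ± 0.05 (limma, adjusted p = 0.000182), Junb at 7.83 with 0.86 ± 0.20, the antiproliferative gene Btg2 at 9.32 with 0.43 ± 0.09, and Fosl2 at 3.63 with 0.24 ± 0.05. Of 16 tested genes 5 passed, 9 when adjusted over the list alone, 10 with the block and 5 within the first batch. Their mean peaked at 8.88 (permutation test, adjusted p = 0.0042; 0.00739 with the block), and this did not pass within the first batch (adjusted p = 0.197). Fisher's exact test passed only with the block (adjusted p = 0.000328; 0.0896 without it). Within the first batch Junb (amplitude 0.50, adjusted p = 0.248) and Fosl2 (0.16, adjusted p = 0.103) did not pass. Junb fell by 2.21 log2 units from circadian time 10 to 18 in the second batch.

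Among cell cycle genes, the replication helicase genes Mcm5, Mcm6 and Mcm7 had amplitudes of 0.32 ± 0.07, 0.25 ± 0.06 and 0.25 ± 0.06. For Mcm7 this rests on a probe set marked for cross-hybridization, and its brightest unmarked one did not pass (amplitude 0.15, adjusted p = 0.0815). With the block they peaked at circadian times 22.9, 23.9 and 0.00525. The cyclin gene Ccnb2 peaked at 22.2 with 0.31 ± 0.07 (limma, adjusted p = 0.0275). Of 20 tested genes 4 passed, 6 when adjusted over the list alone, 8 with the block and 5 within the first batch. Their mean peaked at 22.6 (permutation test, adjusted p = 0.0352; 0.0358 with the block; 0.111 within the first batch), the rhythmic share passed Fisher's exact test only with the block (adjusted p = 0.0408; 0.531 without it), and 10 of the 20 differed in mean level between the batches.

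None of 22 cytosolic ribosomal protein genes and none of 27 respiratory chain genes had a 24 h rhythm by limma, over all genes or adjusted over the list alone (0 in each; 3 and 2 at an unadjusted p under 0.05). With the block 0 and 1 passed. The ribosomal list passed for any phase without the block (permutation test, adjusted p = 0.035) and not with it (0.118) or within the first batch (0.227), and the respiratory chain list did not pass (0.232; 0.316 with the block). Fisher's exact test gave adjusted p of 0.188 and 0.0896 for these lists, and 0.0502 and 0.134 with the block. Between circadian times 10 and 18 of the second batch 4 of the ribosomal genes differed.

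Markers of other cell types were tested for changes in the makeup of the dissected tissue. Among zona glomerulosa and capsule markers 2 of 11 passed, 3 when adjusted over the list alone and 3 with the block. They were Dab2, at circadian time 14.4 with an amplitude of 0.17 ± 0.04, and Vsnl1, at 16.0 with 0.36 ± 0.08. The other tested Dab2 probe sets did not pass over all probe sets (limma, adjusted p of 0.128 or more, and 0.0641 or more with the block). The other Vsnl1 probe set passed (adjusted p = 0.00169, and 0.00052 with the block). Adipose markers passed in 2 of 10 cases, 4 when adjusted over the list alone, with Lep, the leptin gene, peaking at 19.2 with 0.95 ± 0.19 (limma, adjusted p = 0.00905; 0.0048 with the block) and Cidec, a lipid droplet gene, at 14.6 with 0.60 ± 0.16. Endothelial markers passed in 2 of 11, also when adjusted over the list alone, with the tight junction gene Cldn5 at 2.26 with 0.47 ± 0.09 and Emcn at 21.1 with 0.18 ± 0.05. Of 14 leukocyte markers 1 passed, also when adjusted over the list alone, the immunoglobulin gene Ighm at 7.1 with 0.73 ± 0.15 (0.41 on its brightest probe set without a cross-hybridization mark, adjusted p = 0.0218). The remaining Ighm probe sets had amplitudes of at most 0.077 and did not pass (limma over all probe sets, adjusted p of 0.303 or more). Of 14 Schwann, fibroblast and muscle markers 1 passed, also when adjusted over the list alone, the smooth muscle gene Tagln at 22.7 with 0.24 ± 0.06, and 9 of the 14 differed in mean level between the batches. Neither the 5 kidney and liver markers nor the 4 red blood cell markers held a rhythmic gene by limma (0 over all genes and adjusted over the list alone; 0 at an unadjusted p under 0.05 in each). For any phase the glomerulosa list (permutation test, adjusted p = 0.00607; 0.00396 with the block) and the endothelial list (0.00918; 0.0025 with the block; 0.074 within the first batch) passed. The leukocyte list passed only without the block (0.035; 0.154 with it), and the adipose (0.0733), kidney and liver (0.383), red blood cell (0.522) and mixed (0.274) lists did not pass. Within the first batch Cidec (adjusted p = 0.0635), Emcn (0.213) and Tagln (0.119) did not pass. No cell type list passed for a common phase, with or without the block. Fisher's exact test passed for none of these 7 lists (adjusted p of 0.588 for the adipose, 0.831 for the glomerulosa and endothelial and 1 for the other 4 lists; 0.625 or more with the block).

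The next question was which genes differed between the 6 circadian times in any way, including shapes that no single cosine follows. Arntl, Cry1 and Tef had the lowest adjusted p among the genes named above (1.76e-08, 1.18e-08 and 1.76e-08). Hoxd13 was also past the threshold, with 9.95 ± 0.13 at circadian time 10, 8.22 ± 0.21 at 14 and 10.02 ± 1.08 at 18 (log2, SD, n = 3 each). In all, 7493 of 13879 genes passed (limma, moderated F test; 8391 at an unadjusted p under 0.05). This count contains any difference between the array batches, since circadian times 10 and 18 make up the second batch. Between the 4 circadian times of the first batch 1447 genes differed, and between circadian times 10 and 18 of the second 833 differed, 496 higher and 337 lower at 18. Of these 833 genes 419 were also among the 1781 with a 24 h rhythm.

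The 2 cycles in constant darkness were compared at matched circadian times on the 13 profiles with a clear cycle. The second cycle had 1 profile at each circadian time, and so did the first except at circadian time 10. At circadian time 18 the second cycle rests on 78 h replicate 2, with a Gapdh ratio of 0.0386 and Alb at 13.08 (log2). Amplitudes per cycle therefore rest on few profiles. Among genes of the clock with large rhythms, Dbp had an amplitude of 2.42 in the first cycle and 2.33 in the second, and Cry1 1.32 and 1.32 (log2 units). For Per1 they were 0.63 and 1.09, for Csnk1e 0.25 and 0.45, and for Bhlhe40 0.47 and 0.28, with an adjusted p of 0.9998 for each of these differences between cycles. Over 21 rhythmic clock and output genes, with Arntl and its trough at the floor among them, the median ratio of the second to the first amplitude was 0.964, from 0.594 for Bhlhe40 to 1.81 for Csnk1e, and 14 of the 21 lay below 1. No gene differed in level between the cycles (limma, 0 of 13879; 1349 at an unadjusted p under 0.05), and none differed in its rhythm (limma, 0; 324 at an unadjusted p under 0.05; with the block 0 and 810). In simulated data of the same profiles without batch shifts, 196 of 200 level differences of 1 log2 unit and 178 of 200 rhythm differences of amplitude 1 were found. Smaller differences, and data with batch shifts, were not simulated for these tests. The counts of 0 therefore do not show that the cycles are alike.

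A 12 h component beside the 24 h rhythm was found in 58 genes (limma; 3064 at an unadjusted p under 0.05). The lowest p-values belonged to Slc7a2, Hsph1, Nenf, Vkorc1 and Pla2g2f. Slc7a2, a cationic amino acid transporter gene, was at 10.45 ± 0.10 at circadian time 18 and between 10.86 ± 0.18 and 11.26 ± 0.06 at the other times (log2, SD, n = 3; adjusted p = 0.0215). Nenf, a secreted neurotrophic factor gene, was at 11.08 ± 0.24 at circadian time 18 and 1.08 lower at 10 (adjusted p = 0.027), and Vkorc1, the vitamin K epoxide reductase gene, at 11.84 ± 0.08 and 11.22 ± 0.10 (adjusted p = 0.027). Hsph1, an HSP110 chaperone gene, rose from 10.71 ± 0.30 at circadian time 10 to 12.21 ± 0.04 at 14 (adjusted p = 0.027; 0.0111 with the block). Pla2g2f, a phospholipase gene, was at 8.49 ± 0.07 at circadian time 10 and at 9.25 ± 0.13 at 18 (adjusted p = 0.0351). With the block 440 genes passed, 51 of the 58 among them. That fit has 6 terms for 6 circadian times, so it reads the batch only from what the 24 h and 12 h terms leave. Its count holds only if the genes have no shape outside these terms. Without the block the count fell to 7 or fewer without the replicate 1 array of 38, 42, 46, 58, 62 or 74 h or the replicate 2 array of 46 or 50 h, and rose to 103 and 372 without the replicate 2 arrays of 66 and 54 h. Within either batch this component could not be fitted beside the 24 h rhythm, because too few circadian times remain.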

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

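The tests of the near-copies and of the array batches below were chosen after the results had been seen.

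Control probe sets, which no comparison of genes uses, held a signal that stood apart: ThrX-3 read at least 513 on the 8 arrays of 46, 54, 70 and 78 h and at most 101 on the other 16. Of the 3993 tested probe sets without 1 gene symbol, 248 had a 24 h rhythm (limma, adjusted p under 0.05), 438 with the array batch as a block and 219 in both fits. The array of 78 h replicate 2 had a ratio of 5' to 3' Gapdh signal of 0.0386, against 0.822 to 0.978 on the other 7 of these 8 arrays and 1.03 to 1.15 on the other 16, so that this measure of RNA quality moves with the array batch.

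The near-copies were weighed against 3 explanations. Separate samples are argued against by the spread within the 6 pairs, whose widest value was 0.193 of the narrowest among 30 other pairs of the same circadian time. A flat distribution of ratios within 5%, which a column computed from another with an even random factor would give, was met in every pair, with a Kolmogorov distance of at most 0.00594, so that this may be their origin, and in each pair 1 column was written in another number format. A repeated measurement or scaling of 1 array is argued against by the same ratios, which were flat and bounded within 5% in every pair. A single scaling factor would give 1 ratio for all probe sets. The spread at dim over that at bright probe sets was at most 1.01 in the pairs and had a median of 2.03 in other pairs. This comparison alone decides nothing, since 5 of those 30 lay at 1.2 or below, with the lowest at 0.912. All 5 were pairs of 54 and 78 h arrays, and the lowest of the others was at 1.36. No biological explanation was tested, since 5 of the 6 pairs join different time points, and nothing here says how the columns came about.

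The arrays of circadian times 10 and 18 were weighed in the same way, since a rhythm of the tissue would also set them apart. A smooth 24 h rhythm is argued against: over 6211 genes that differ between these arrays and circadian times 2, 6 and 22, the median share of that difference at circadian time 14, which lies between them, was 0.0573 (quartiles -0.137 and 0.316). Skeletal muscle and liver are argued against as the whole cause by positions on the first principal component, from 0 at the first batch mean to 1 at that of the second: the 2 second-batch profiles lowest in Acta1 (6.37 and 7.93, at most 0.388 of the way between the batch means of that gene) lay at 0.943 or more, as did the 4 with Alb and Ttr within the first batch's range. A difference in array processing is a candidate source: 6 of 44 bacterial control probe sets other than ThrX-3 did not overlap between the batches. Chance would give 0.0047 for separate controls, but several of the 6 measure the same control, bioB, so this comparison overstates the evidence. Of the 6, 2 were higher in the second batch and the others lower. Blood stays open, as 0 of 6 second-batch profiles had Hba-a1 within the range of the first batch, and so do RNA quality, whose measure moves with the batch, and, untested, a biological difference at circadian times 10 and 18 themselves.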

How the results depend on the processing

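Fits with the array batch, with single batches, with 24 columns and with both columns of a pair left out were chosen after the results had been seen. No result reversed, and the counts of 0 for both comparisons of cycles stayed at 0 in every fit that was run. The count of 24 h rhythms (1781) was 2743 over all probe sets, 26 without replicate 1, 152 without replicate 2, 955 over time point means, 537 with the time point as a random block, 4193 with 24 columns and 4615 with 24 columns and the batch block. Leaving out single arrays or pairs gave 1178 (without 46 h replicate 1) to 2212 (without 50 h replicate 1 and 74 h replicate 2). Leaving out a replicate number removes 12 columns, and for the other changes the cause was not tested. Rhythms with a ratio of 2 or more (127) numbered 76 with the 4 times larger offset, 224 over all probe sets, 21 without replicate 1, 45 without replicate 2, and 97 to 191 without single arrays or pairs (highest without 50 h replicate 1 and 74 h replicate 2). Genes with any difference (7493) numbered 14321 over all probe sets, 1448 without replicate 1, 1447 in the first batch, 833 in the second, and 6499 to 7898 without single arrays. The 12 h component (58) was the least stable: 33 without the filter, 35 without trend, 12 over time point means, 440 with the batch block, 454 with it without 78 h replicate 2, 106 with it without muscle profiles, 3285 with 24 columns, 2188 with 24 columns and the block, 0 and 1 without replicate 1 or 2, and 0 (without 38, 42 or 74 h replicate 1) to 372 (without 54 h replicate 2). With the replicate number as a block, 6 genes had a 12 h component, 1547 a 24 h rhythm and 115 a ratio of 2 or more. The replicate numbers do not pair the samples: the deviations of same-numbered profiles correlated with a median of -0.0168 over 66 pairs, and 34.8% lay over 0.1. Lists with a rhythm in any phase (16 of 21) numbered 8 and 9 without replicate 1 or 2, and with a common phase (6) 3 and 1. Of 67 rhythmic named genes 13 passed in every setting and 54 were lost in at least 1. Of the 21 others 12 passed in none. Signal over background limits dim genes, since probe sets under a signal of 184 were not tested.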

Other observations

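The tests of the Pnmt rhythm and of the 12 h terms against the array batch were chosen after their results had been seen, as were the genes in the next paragraph.

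Members of the heat shock and endoplasmic reticulum lists that the naming rule left out also cycled. Hspa1a, an inducible HSP70 gene, peaked at circadian time 16.7 with an amplitude of 0.67 ± 0.15 (SE, n = 18), and Fkbp4, a co-chaperone of steroid receptors, at 19.9 with 0.52 ± 0.11. Hspa5, the main chaperone of the endoplasmic reticulum, peaked at 14.4 with 0.16 ± 0.04 and Manf, a secreted stress factor, at 14.8 with 0.19 ± 0.05. In the cholesterol list Fdps and Idi1, which act on isoprenoid precursors, had amplitudes of 0.73 ± 0.11 and 0.73 ± 0.11, with peaks at 19.5 and 17.9. All 6 were past the limma threshold of 0.05, and within the first batch Hspa1a (adjusted p = 0.0777) and Hspa5 (0.0607) were not.

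Pnmt peaked in the projected night while other chromaffin genes did not follow it, and a change in the share of medulla in the dissected gland was tested as a cause. It is argued against: at the phase of Pnmt, the other 17 chromaffin genes had a median rhythm of -0.0522 of its amplitude (quartiles -0.144 and -0.0314), and 4 were positive. The array batch is argued against too, since Pnmt passed within the first batch alone (limma, adjusted p = 5.22e-05). A rhythmic control of Pnmt itself may therefore be considered as a hypothesis, found and tested on the same data. Circulating glucocorticoid was not measured here.

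Random orders of the profiles were fitted like the real one to see whether chance could give as many genes. For the 24 h rhythm only the real order among 100, that is 1, reached 1781 genes, and the highest other gave 108. With the batch as a block and orders within batches it was again 1 of 100, with 2475 genes against 50. For ratios of 2 or more it was 1 of 100 both without the block (127 against 29) and with it (124 against 9). For any difference between circadian times it was 1 of 100 over all profiles (7493 against 719) and 1 of 100 within the first batch (1447 against 207). These orders argue against chance for each of these counts taken alone. A share of 1 in 100 is the smallest that they can give, and it was not adjusted over the counts. Orders over all profiles also mix the array batches, so for the counts of 1781, 127 and 7493 they do not tell an effect of time from a difference between batches. For the 12 h component 2 of 100 orders gave at least 58 genes and the highest other 1011, and with the block 3 of 100 gave at least 440 and the highest other 494. These shares lie under 0.05, but they were not adjusted over the counts tested here. The count of 58 also fell to 0 without the replicate 1 array of 38, 42 or 74 h. Chance is therefore not firmly excluded for the 12 h component. What set the order with 1011 genes apart was not identified. Its 12 h terms carried 0.6 of the batch difference left by the 24 h terms, the most of the 99 other orders (median 0.0909; 0.333 in the real order). This is 1 order picked for its count, only 2 of the 99 gave any gene, and over the 99 this share and the count had a rank correlation of 0.218. For the comparisons of cycles the real count was 0, which each of 96 splits reaches (96 of 96), so these splits decide nothing; the highest others were 13 for the level and 1 for the rhythm.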
